A study of Homo sapiens with 10 samples.

How the data were processed

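Total RNA from A549 cells was extracted, converted to biotin-labelled cRNA and hybridised to Illumina BeadChip arrays, 1 array per sample, per the labels' protocols. Each feature is a set of beads that carry 1 probe, and its signal is the mean brightness of those beads.

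The deposited non-normalized table holds, per the file headers, the mean bead signal, its standard error, the number of beads and a detection p for each row and array. The signals are intensity values on a linear scale that the authors deposited without normalization between arrays. The detection p-value per row and array was deposited with them, and it comes from BeadStudio, which is named in the submitters' processing notes with limma and lumi and without versions. How the background was treated before export is not given in the sources used here. The lowest signals lie at 41.2 to 105 and none is below 0.

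The table has 37846 rows, of which 25200 carry a gene symbol and 12646 stand for clusters of expressed sequence tags without a symbol. It has 1 row per symbol. In 6974 rows the bead number is not whole on at least 1 array, so these are means over several probes, none of them a tag cluster row. How far the probes of such a gene differ from each other cannot be seen in the table. Gene identifiers were matched to a table of current human gene names (assembly GRCh38.p14), which named 20467 of the rows with a symbol (81.2%) and changed the symbol of 4830. The file's own symbol was kept otherwise. Chromosomes are those of the file, and no coordinates were used.

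A second deposited table holds the authors' processed values for 13003 rows, which were used here as log2 values. All 13003 rows have a detection p under 0.01 on at least 1 array, and 1 further row that does is not among them. The ranks within each column were the same as those of its own array's signals (rank correlation 1.00 across rows, against at most 0.956 with any other array), so the values run in the same direction. The values lie between 6.87 and 14.8. The column medians were 7.442, 7.450, 7.449, 7.455 and 7.449 for control replicates 1 to 5 and 7.470, 7.465, 7.444, 7.466 and 7.469 for silica replicates 1 to 5. The distributions were nearly equal, genes were not centred, and the transform and the normalization method behind them stay unknown. Differences between these values were read as log2 fold changes, which the unknown transform may not warrant. This table served only as an alternative.

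Samples were grouped by the silica dose in their labels, and all 10 columns of signals were matched to a sample by name. The steps of limma's neqc function were used: normexp background correction, an offset of 16, quantile normalization over all rows, and log2. neqc takes the background's mean and SD from the detection p, which assumes that p falls as the signal rises. That order does not hold in rows averaged over probes. Background mean and SD were therefore taken from the tag cluster rows alone, a change from the planned correction made on seeing the file, and the version from all rows was run as an alternative. The background means were 63.6 to 71.0 on 8 arrays, with SDs of 6.00 to 6.81, and 173 and 175 on the 2 bright arrays, with SDs of 18.1 and 19.3. The size of fold changes of dim genes depends on the correction and the offset: 403 rows changed at least 2-fold with them and 159 without background correction.

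Rows were kept when their detection p was under 0.05 on at least 5 of the 10 arrays, which left 10682. Among rows that now share a gene name, the one with the highest mean was kept, and 36 were dropped. The 10646 rows tested comprise 9856 with a symbol and 790 tag clusters. The filter is strict on averaged rows: 634 rows failed it although their signal exceeded the background mean by 2 SD on at least 5 arrays, and all 634 were averages of several probes. *CDKN1A* is an example of this behaviour that passed, with mean log2 signals of 9.15 and 10.6 but detection on 1 of 5 control and 4 of 5 silica arrays.

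Groups were compared with limma's lmFit and eBayes on log2 values, two-sided, with group as the only term and Benjamini-Hochberg adjustment over the rows tested. Errors of log2 fold changes are the moderated standard errors. A gene whose detection p was not under 0.05 on any array of 1 group was not above background there and has only a bound. Its fold is given as at least the bright group's mean over the dim group's mean, where each dim array contributes the higher of its lowest detected log2 signal and the gene's own value. The 29 gene lists, of 699 genes of which 523 were measured, were tested with limma's camera (correlation preset to 0.01, adjusted over the 28 lists with at least 5 measured members), and again with an estimated correlation and with fry. Fry tests whether a list's genes move one way on balance and does not compare them with other genes.

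The groups, the test, the lists, the rule for naming genes and most alternative settings were fixed before the data were examined. The rule named the 12 genes with the largest rises and the 12 with the largest falls among those past the threshold whose groups did not overlap, leaving out provisional symbols. It also named up to 4 genes per list with the largest changes past the threshold, or the largest change where none passed, and *CXCL8*, *IL6*, *HMOX1* and *CDKN1A* in any case. It gave 108 genes, of which 105 passed. Values of 4 of these genes are not reported here, and single arrays were examined in the other 104.

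The procedure was tested on simulated data: in 10646 simulated rows with the real means and spreads, limma recovered 30% of 50 rows changed by 0.5 on the log2 scale, 94% of 50 changed by 1, and 100% of 50 changed by 2 and of 50 changed by 3. Of its calls 4.71% (8 rows) were unchanged rows. A far smaller share of rows was changed there than the 22.4% called in the data, so these shares do not measure the sensitivity in the data. In a second simulation with 1 of 28 lists lowered by 0.5, that list alone was called. The simulated rows were independent, while the real cytokine list had an estimated correlation of 0.14. The error rate of the list test with correlated genes was therefore not examined. The median within-group SD of the real rows was 0.23 on the log2 scale, and the smallest change called was 0.27.

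The 95th percentile of an array's signals was 6.24 to 7.99 times its median, which is near background. Correlations across rows were 0.979 to 0.985 between arrays of a group and 0.951 to 0.965 between groups, and genes are not independent replicates. The 2 arrays that read brighter, by 2.63 times, were treated as a batch in added alternatives. Other alternatives changed the background correction, the normalization, the filter, the row rule, the test, the threshold and the arrays used. No column names a slide or a scan. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for tables and figures.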

Results

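Gene expression was measured in A549 cells, a human line derived from a lung adenocarcinoma and widely used as a model of the lung epithelium. The 10 samples formed 2 groups of 5. One group received 800 µg/ml crystalline silica, a mineral dust, for 6 hours in serum-free medium, and the other received 0 µg/ml for the same time. The comparison asks which genes respond in lung epithelial cells exposed to silica, within a study of silica-induced lung toxicity. Each sample was hybridised to its own Illumina BeadChip array, and 10820 to 12756 of the 37846 rows were detected per array at a detection p under 0.05. The median signal was 67.8 to 75.8 on 8 arrays and 188 and 189 on control replicate 1 and silica replicate 3. The number of arrays limits the precision of every value. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

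Silica-exposed cells had far higher signals of immediate early transcription factors and of inflammatory mediators than control cells. *FOS*, a subunit of the AP-1 transcription factor encoded on chromosome 14, rose from 4.96 ± 0.27, near the detection floor, to 11.75 ± 0.34 on the log2 scale (mean ± SD, n = 5 per group). *CXCL8*, the neutrophil chemoattractant interleukin-8 on chromosome 4, rose 57.9-fold from a level that was already high, 8.82 ± 0.13 against 14.68 ± 0.11. *IL6* on chromosome 7, a cytokine of the acute phase response, rose from 4.85, with detection on 1 of 5 control arrays, to 10.42. Where control cells were so dim, the size of the change rests on the background correction and the offset. In the authors' processed values, read as log2 although their transform is unknown, the differences were smaller. They were 4.35 in place of 6.79 for *FOS*, 5.38 in place of 5.86 for *CXCL8* and 3.09 in place of 5.57 for *IL6*. The falls were smaller. The deepest was that of *MAT2A* on chromosome 2, the enzyme that makes S-adenosylmethionine, which was 4.49-fold lower (12.24 ± 0.08 against 10.08 ± 0.37).

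Of 10646 rows tested, 2381 changed at an adjusted p under 0.05 in limma, 972 of them higher and 1409 lower in silica. The excess of falls depends on the normalization, with 1150 higher and 1128 lower under cyclic loess and 596 and 1250 under median scaling. Without any normalization between arrays 188 rows passed, all of them at least 2-fold and all among the 2381. Of these 79.3% were higher, against 40.8% of the 2381. The shares cover changes of different size, so they do not show a shift in direction. The median log2 fold change of all rows was -0.08 without normalization and -0.02 with it. Large changes went mainly upward. Among the 403 rows that changed at least 2-fold, 273 were higher and 130 lower, and among the 79 that changed at least 4-fold, 75 were higher and 4 lower. The count of 403 rests on the background correction: it was 159 without one. The 4-fold counts depend on the correction too, with 44 higher and 1 lower without one. In the authors' processed values of the same rows, whose transform is unknown, 108 changed at least 2-fold, and 29 were higher and 0 lower at 4-fold. Leaving out 1 array at a time gave 71 to 77 higher and 2 to 5 lower at 4-fold. The 5 silica and 5 control values did not overlap in 1884 rows, which is 17.7% of the rows where chance would give 0.794%. The first principal component carried 51.3% of the variance and separated the groups. With the scan brightness of the arrays as a block, 2373 rows changed, and among the 8 arrays of ordinary brightness 1942 did. The bright pair holds 1 array per group, which is too few for a test of its own. Both of these fits were chosen after the data had been seen.

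**Figure D1:**
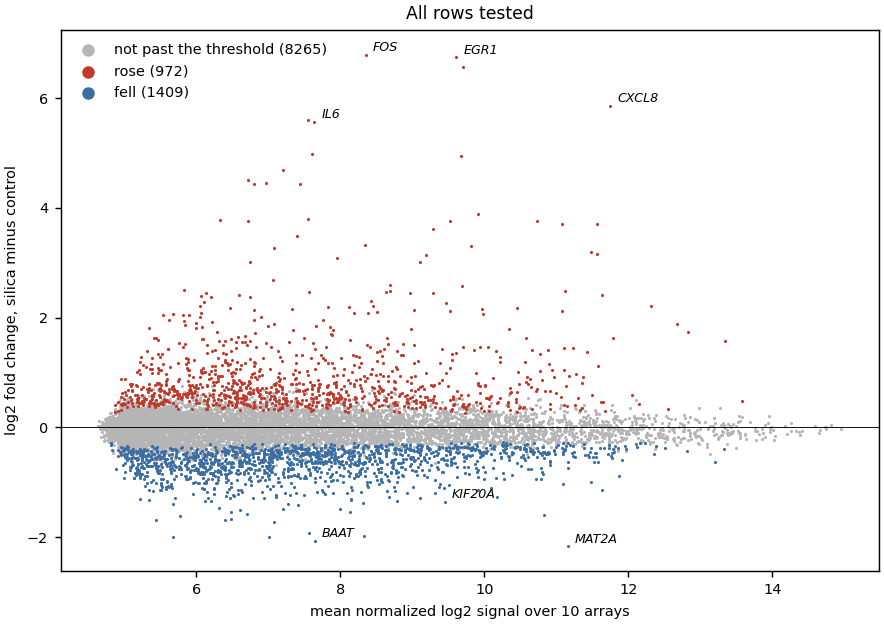
Log2 fold change (silica minus control, vertical axis) of each of the 10646 rows tested against its mean normalized log2 signal over the 10 arrays (horizontal axis). The 972 rows that rose are red, the 1409 that fell are blue, and the rest are grey. Rises reach 6.79 (*FOS*), while the deepest fall of a named gene is -2.17 (*MAT2A*).

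The 12 named genes with the largest rises included transcription factors and secreted signals. After *FOS* came *EGR1*, a zinc finger transcription factor, with a log2 fold change of 6.75 ± 0.16 (SE, adjusted p = 1.0e-11), and *FOSB*, another AP-1 subunit, with 6.57 ± 0.12 (adjusted p = 1.1e-12). The chemokine genes *CXCL8* (5.86 ± 0.10, adjusted p = 7.0e-13), *CXCL2* (5.61 ± 0.15) and *CCL20* (4.45 ± 0.20) and the cytokine gene *IL6* (5.57 ± 0.13, adjusted p = 9.4e-12) were among them. So were *PTGS2*, the inducible cyclooxygenase (4.94 ± 0.14), *GEM*, a small GTPase (4.99 ± 0.17), *NR4A2*, an orphan nuclear receptor (4.69 ± 0.17), and *TNFAIP3*, a ubiquitin-editing inhibitor of NF-kappaB (4.43 ± 0.14). *CSF2*, which encodes the growth factor GM-CSF, was not above background on any control array and was at least 19.8-fold higher in silica under this background correction (adjusted p = 3.8e-11), while its log2 fold change was 1.61 with the background taken from all rows. Several of the others were dim in control cells as well. *IL6* and *CXCL2* were each detected on 1 of the 5 control arrays, and *FOS* on 3. The authors' values gave 3.04 for *CXCL2*, 2.76 for *GEM*, 2.32 for *TNFAIP3* and 2.31 for *NR4A2*, and *CCL20* had 1.89 with the background taken from all rows. The rule for naming these 12 genes required all 5 silica values to lie above all 5 control values, so that separation is not a result.

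The 12 named genes with the largest falls had varied known roles. After *MAT2A* (-2.17 ± 0.16, SE) came *BAAT*, an enzyme of bile acid conjugation, with a log2 fold change of -2.06 ± 0.11 (adjusted p = 4.5e-08), *HILPDA*, a lipid droplet protein, with -2.01 ± 0.18 (detected on 1 of the 5 silica arrays, and -0.22 with the background taken from all rows), and *PDE7B*, a cyclic AMP phosphodiesterase, with -2.00 ± 0.19. *FZD2*, a Frizzled receptor for Wnt proteins, had -1.98 ± 0.18 (adjusted p = 5.6e-06) and *LGR4*, a receptor for R-spondins, had -1.67 ± 0.12. *AXIN2*, an inhibitor of Wnt signalling, was not above background on any silica array. It was at least 3.04-fold lower there under the main background correction (adjusted p = 2.3e-07). The bound holds only for that correction, since its log2 fold change was -0.15 with the background taken from all rows. *SKP2*, the substrate receptor of a ubiquitin ligase that acts on cell cycle inhibitors, had -1.72 ± 0.14. *TNS3*, a focal adhesion protein, had -1.59 ± 0.14, and *SUOX*, sulfite oxidase, had -1.58 ± 0.11. *AQP11*, an aquaporin, had -1.62 ± 0.22, and *ZNF30*, a zinc finger gene, had -1.69 ± 0.18. Most of these falls were far smaller with the background taken from all rows: -0.17 for *AQP11*, -0.28 for *ZNF30*, -0.30 for *LGR4*, -0.34 for *SUOX*, -0.51 for *SKP2*, -0.57 for *PDE7B* and -1.04 for *BAAT*. Here too the naming rule required all 5 silica values to lie below all 5 control values.

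**Figure D2:**
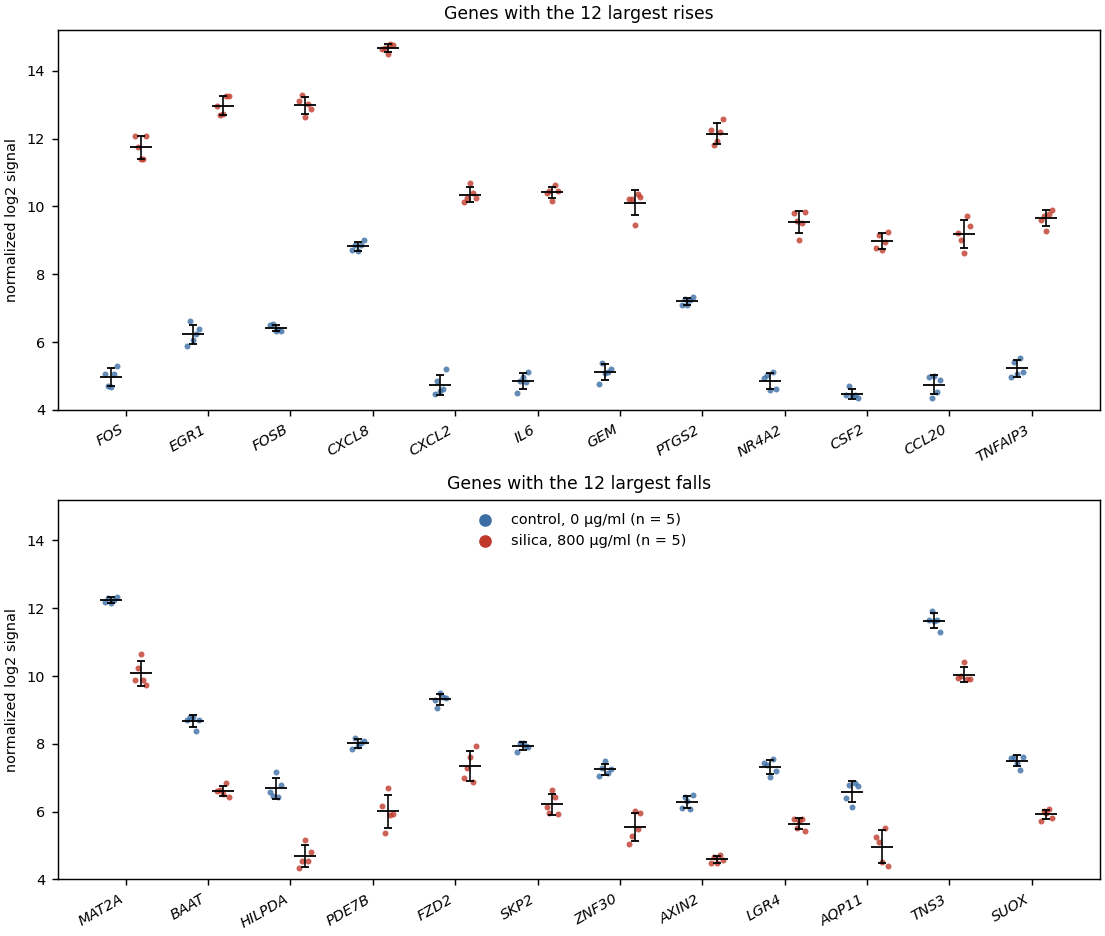
Normalized log2 signal (vertical axis) of each array for the genes with the 12 largest rises (top) and the 12 largest falls (bottom). Blue points are the 5 control arrays and red points the 5 silica arrays, and the bars are mean ± SD. *CXCL8* had the highest silica mean, 14.68. No gene shown has overlapping groups, since the rule for naming genes required this.

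Inflammatory mediators and NF-kappaB feedback genes rose together. Of 22 listed cytokines and chemokines 14 were measured. Of these 13 rose and 0 fell (the same number, 13, when adjusted over the list alone), with a median log2 fold change of 3.39. A gene not detected in control cells passed the detection filter only if it was detected on all 5 silica arrays, as *CSF2* was. The share of measured members that rose is therefore partly set by the filter, here and in the other lists. Besides the genes above, *CCL5* had a value of 0.18 that did not pass. Of 18 measured genes of NF-kappaB feedback, which encode inhibitors and subunits of that factor and its survival targets, 14 rose and 0 fell (16 rose when adjusted over the list alone). The survival factor *BIRC3* rose by 3.77 on the log2 scale, *IER3* by 3.16 and *NFKBIZ* by 2.46. The lists had adjusted p = 2.1e-25 and adjusted p = 9.8e-17 in limma's camera test with the preset correlation. With an estimated correlation both held in camera, but at the far weaker adjusted p = 0.0014 and adjusted p = 4.7e-04.

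Of 27 listed immediate early genes 21 were measured. All 21 rose, and the count was the same when adjusted over the list alone. Their median log2 fold change was 1.93 (camera adjusted p = 5.5e-31). Of 18 measured genes of MAPK feedback and EGFR ligands, 13 rose and 0 fell (14 rose when adjusted over the list alone), with a median of 1.51 (camera adjusted p = 1.2e-12). *HBEGF*, a ligand of the EGF receptor, had a log2 fold change of 3.48 ± 0.14, and *DUSP5*, a phosphatase that inactivates ERK, had 3.20 ± 0.13. *PHLDA1* (2.41 ± 0.15) and the MAPK pathway inhibitor *SPRY4* (2.09 ± 0.12) rose as well. With the background taken from all rows *HBEGF* had 1.72 and *SPRY4* 0.28. Both lists held in camera with an estimated correlation, at the weaker adjusted p = 3.3e-05 and adjusted p = 0.0042.

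Genes of the integrated stress response rose more often than they fell. Of 20 measured members 10 rose and 2 fell (14 and 2 when adjusted over the list alone; camera adjusted p = 2.5e-08). *DDIT3*, the transcription factor CHOP, had a log2 fold change of 3.80 ± 0.16, *PPP1R15A*, which directs dephosphorylation of the initiation factor eIF2alpha, had 3.70 ± 0.11, and *TRIB3*, a pseudokinase, had 2.14 ± 0.13. The transcription factor *CEBPB* had 1.89 ± 0.12. In the authors' values *DDIT3* had 2.05. The members that fell were *SLC7A5* and *PSPH*, an amino acid transporter and an enzyme of serine synthesis, named here after their values were seen. Of 18 measured endoplasmic reticulum chaperone and degradation genes 4 rose and 0 fell (4 and 0 when adjusted over the list alone), and the list was called (camera adjusted p = 0.0018, median 0.17). They were *DNAJB9* (1.16 ± 0.12), *XBP1* (0.99 ± 0.11), *HERPUD1* (0.84 ± 0.09) and *CALR*, whose smaller change of 0.45 ± 0.13 lost its call when any of 5 of the 10 arrays was left out.

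Targets of the tumour suppressor p53 were called as a list (camera adjusted p = 0.0053), with 6 of 20 measured members higher and 2 lower, both over all rows and when adjusted over the list alone. *GDF15*, a secreted stress-induced cytokine, had a log2 fold change of 3.89 ± 0.12, *GADD45A* 2.45 ± 0.14 and *AEN*, an exonuclease, 1.47 ± 0.13. *CDKN1A*, the cyclin-dependent kinase inhibitor p21, had 1.41 ± 0.13 (9.15 ± 0.19 against 10.56 ± 0.19, SD). The members that fell were *XPC* and *SESN1*, a DNA damage sensor and a stress-induced growth inhibitor, again named after their values were seen. Of 22 measured hypoxia and glycolysis genes 7 rose and 1 fell (7 and 1 when adjusted over the list alone; camera adjusted p = 0.0010), all by less than 2-fold. *PFKFB4* had 0.89 ± 0.17, the glucose transporter gene *SLC2A3* 0.75 ± 0.11, the vasodilator peptide gene *ADM* 0.59 ± 0.11 and *VEGFA* 0.56 ± 0.12, the last detected on 3 control and 2 silica arrays and at 0.04 with the background taken from all rows. The member that fell was *SLC2A1*, another glucose transporter gene.

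Genes of the extracellular matrix and the plasminogen system were called as a list (camera adjusted p = 1.1e-04). Of 18 measured members 8 rose and 1 fell (9 and 2 when adjusted over the list alone). *MMP10*, the metalloproteinase stromelysin-2, was not above background on any control array. Under the main background correction it was at least 19.7-fold higher in silica (adjusted p = 1.2e-10). That bound does not hold for the log2 fold change of 1.65 with the background taken from all rows. The urokinase receptor gene *PLAUR* had a log2 fold change of 1.95 ± 0.11. The collagen gene *COL1A1* fell, with -1.28 ± 0.16. That background gave 1.06 for *PLAUR* and -0.22 for *COL1A1*. The list of TGF-beta and YAP targets was not called (camera adjusted p = 0.757). Of its 16 measured members 2 rose and 5 fell (3 and 5 when adjusted over the list alone). *ANKRD1* (1.12 ± 0.21) and *ID3* (0.93 ± 0.12) were higher, while *ID1* (-1.40 ± 0.19) and *SMAD6* (-1.38 ± 0.15) were lower, and the background from all rows gave 0.15 for *ANKRD1* and -0.49 for *ID1*.

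Mitosis genes fell as a group. Of 26 measured members 15 fell and 0 rose (18 fell when adjusted over the list alone), with a median log2 fold change of -0.46 (camera adjusted p = 2.4e-07). The kinesin gene *KIF20A* had -1.35 ± 0.10, the kinetochore gene *CENPF* -1.10 ± 0.10, the cyclin gene *CCNA2* -1.04 ± 0.14 and the topoisomerase gene *TOP2A* -0.89 ± 0.10. Of 27 measured DNA replication genes 6 fell and 0 rose in limma (6 and 0 when adjusted over the list alone, 7 and 0 at an unadjusted p under 0.05). The list was not called (camera adjusted p = 0.218), but fry called it (adjusted p = 4.1e-06), as did camera without the detection filter. *POLE2*, a polymerase subunit gene, had 8.92 ± 0.20 in control and 7.92 ± 0.21 in silica (SD), *FEN1* a log2 fold change of -0.83 ± 0.11 and *MCM3* -0.39 ± 0.09. Of 19 measured DNA repair genes 4 fell and 0 rose (3 and 0 when adjusted over the list alone), among them *ERCC5* (-0.64 ± 0.15, and -0.11 with the background taken from all rows) and *RAD51C* (-0.58 ± 0.10). That list had camera adjusted p = 0.0410, and its call was lost with adjusted p = 0.0869 with an estimated correlation.

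**Figure D3:**
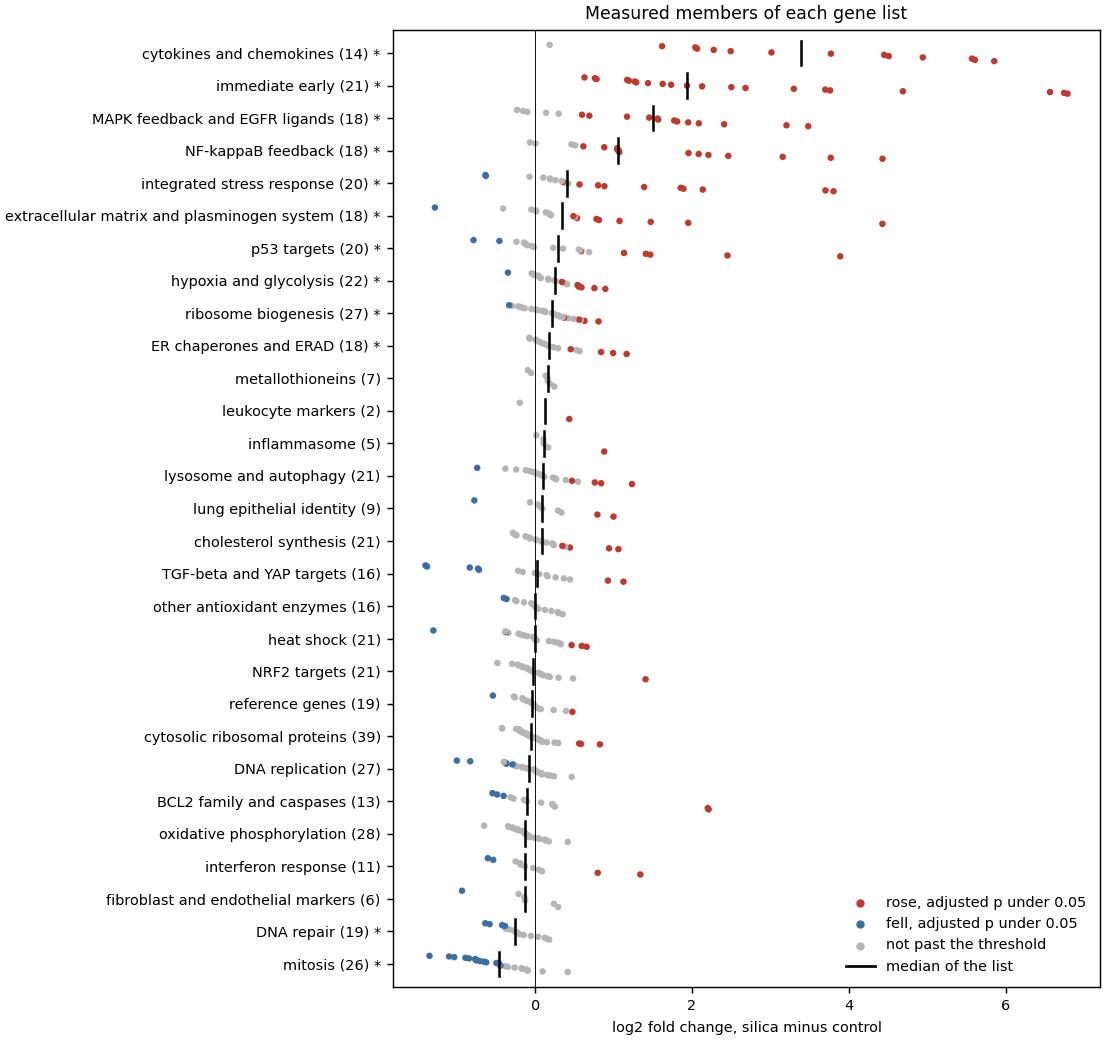
Log2 fold change (silica minus control, horizontal axis) of every measured member of the 29 gene lists, ordered by list median (black bars), with the number measured in brackets. Red points rose, blue points fell and grey points did not pass. The 12 lists with an asterisk were called by camera: 10 higher, led by cytokines and chemokines with a median of 3.39, and 2 lower, mitosis with a median of -0.46 and DNA repair with -0.26. DNA repair and ribosome biogenesis, the latter among the 10, lost their calls with an estimated correlation (0.0869 and 0.135).

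Lists of oxidant defence genes were not called. Of 21 measured NRF2 targets only *OSGIN1* rose (1.41 ± 0.13) and 0 fell, a count that was the same when adjusted over the list alone (camera adjusted p = 0.935). *HMOX1*, heme oxygenase, had a value of 0.48 ± 0.16 with adjusted p = 0.0521, just outside the threshold, and it passed in 10 of 27 alternative settings. Of 20 other antioxidant enzyme genes 16 were measured, of which 0 rose and 2 fell (0 and 1 when adjusted over the list alone, camera adjusted p = 0.980). The 2 were *PRDX3* (-0.37 ± 0.09) and *MSRB2* (-0.40 ± 0.12), and the call of *MSRB2* was lost when any of 7 arrays was left out. Of 10 metallothionein and zinc transporter genes 7 were measured, and none of these passed in limma. This held at an adjusted p over all rows, over the list alone, and at an unadjusted p under 0.05 (0 genes). The largest value was 0.24 ± 0.19 for *MT1G* (camera adjusted p = 0.441). Of 21 heat shock genes 3 rose and 2 fell (3 and 2 when adjusted over the list alone; camera adjusted p = 0.600). *CRYAB* (0.65 ± 0.10, and 0.23 with the background taken from all rows) and *DNAJB1* (0.46 ± 0.12) were higher. *HSPA1L* was not above background on any silica array and was at least 2.31-fold lower under the main background correction. The bound holds only for that correction, since its log2 fold change was -0.11 with the background taken from all rows.

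Cell death, interferon and organelle lists were not called either. Of 24 genes of the BCL2 family and caspases 13 were measured, and members that were not measured could not be assessed. Among the 13 measured, 2 rose and 3 fell (2 and 3 when adjusted over the list alone, camera adjusted p = 0.757). The pro-apoptotic *PMAIP1* (2.21 ± 0.21) and the anti-apoptotic *MCL1* (2.20 ± 0.15) both rose. Of 14 inflammasome genes only 5 were measured (camera adjusted p = 0.218). Among these only *PANX1*, a channel that releases ATP, rose (0.88 ± 0.16, and 1 gene when adjusted over the list alone). Of 27 interferon response genes 11 were measured (camera adjusted p = 0.980). Among these 2 rose, *ISG20* (1.34 ± 0.10) and *IRF1* (0.80 ± 0.14), and 2 fell, among them *STAT2* (-0.61 ± 0.11). The counts were 2 and 2 when adjusted over the list alone. Of 21 lysosome and autophagy genes 4 rose and 1 fell (5 and 1 when adjusted over the list alone; camera adjusted p = 0.142), and the list was called without the detection filter (0.0354) and with detection on all 10 arrays (0.0352). The sialidase gene *NEU1* had 1.23 ± 0.17, *MAP1LC3B* 0.84 ± 0.20 and the kinase gene *ULK1* -0.74 ± 0.11. Of 21 cholesterol synthesis genes 4 rose and 0 fell (4 and 0 when adjusted over the list alone; camera adjusted p = 0.228), led by *INSIG1* (1.06 ± 0.13), a regulator of the pathway. With the background taken from all rows some of these values were smaller: 0.32 for *PMAIP1*, 0.08 for *PANX1*, 0.39 for *IRF1* and 0.21 for *NEU1*. In the authors' values *MCL1* had 1.27.

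Few single genes of energy metabolism and of the ribosome passed the threshold. None of 28 oxidative phosphorylation genes passed in limma, over all rows or when adjusted over the list alone, while 5 were lower and 0 higher at an unadjusted p under 0.05 (camera adjusted p = 0.225). That list was called by fry (adjusted p = 7.1e-04) and by camera without the detection filter. The largest value was that of *COX7B*, -0.65 ± 0.24 (adjusted p = 0.0736). Of 39 cytosolic ribosomal protein genes 3 rose and 0 fell, and 0 passed when adjusted over the list alone (3 rose at an unadjusted p under 0.05; camera adjusted p = 0.970). These were *RPL23* (0.82 ± 0.24), *RPL14* (0.58 ± 0.17) and *RPL7* (0.56 ± 0.19), and the first pair lost their calls when any of 4 arrays was left out and *RPL7* when any of 8 was. With the background taken from all rows *RPL14* had 0.09 and *RPL7* 0.28, and neither passed. Of 27 ribosome biogenesis genes 4 rose and 1 fell (4 and 1 when adjusted over the list alone), led by *RRP12* (0.81 ± 0.11), *NOLC1* (0.63 ± 0.11) and the helicase gene *DDX21* (0.56 ± 0.13). This list had camera adjusted p = 0.0335, a call that was lost with adjusted p = 0.135 with an estimated correlation. In the authors' values *RRP12* had 0.44 and *NOLC1* 0.40.

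Few markers of lung epithelium or of other cell types were measured. Of 25 epithelial identity genes 9 were measured and 2 rose, the mucin gene *MUC5AC* (1.00 ± 0.15) and the keratin gene *KRT19* (0.79 ± 0.14), and 1 fell, the E-cadherin gene *CDH1* (-0.78 ± 0.09), with 3 and 1 when adjusted over the list alone (camera adjusted p = 0.247). With the background taken from all rows these had 0.12, 0.28 and -0.18. Of 21 leukocyte markers 2 were measured, which is too few for the list test. Of these *CD68*, also a lysosomal protein of other cells, rose (0.43 ± 0.11, and 0.13 with that background; 1 when adjusted over the list alone). Of 20 fibroblast and endothelial markers 6 were measured and *COL3A1*, detected on 1 of 5 silica arrays, fell (-0.94 ± 0.18, and -0.08 with that background; 1 when adjusted over the list alone) (camera adjusted p = 0.922). Of 19 reference genes 1 rose and 1 fell, the latter *IPO8* (-0.54 ± 0.14, and -0.32 with that background), with 1 and 1 when adjusted over the list alone (camera adjusted p = 0.960). The direction of *IPO8* was the same under quantile normalization, median scaling, cyclic loess and no normalization, although it did not pass without normalization. The median of the reference genes was -0.04 with quantile normalization and 0.08 with median scaling.

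Of the 28 lists with at least 5 measured members 12 were called, 10 higher and 2 lower, and 10 were called with an estimated correlation, all but DNA repair and ribosome biogenesis. With that correlation the camera adjusted p of the 10 ran from 3.3e-05 (immediate early) to 0.0326 (endoplasmic reticulum chaperones and degradation). The smaller values given with the preset correlation thus depend on that setting. The median, the mean and the camera direction differed in sign in 6 lists that were not called: NRF2 targets, other antioxidant enzymes, heat shock, BCL2 family and caspases, interferon response, and TGF-beta and YAP targets. With scan brightness as a block and without the 2 bright arrays, 12 lists were called each time.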

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

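The tests of scan brightness were chosen after the brightness of the arrays had been seen, and the count over other splits of the arrays was set in advance. The measures and genes below are those in which 1 of the 5 arrays of a group stood far from the other 4. The gap to the nearest array, as a share of the whole range, had to exceed 0.71, which chance alone does in about 1 of 20 groups.

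Of 8 tests of array measures 3 exceeded that value. Control replicate 1 had a median signal of 188 where the control median was 73.6 (share 0.940), and silica replicate 3 had 189 where the silica median was 72.5 (share 0.941). Control replicate 1 also had 12756 rows detected, against a group median of 11609 (share 0.757).

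Each group held 1 bright array, so brightness alone would not separate the groups. It does not account for the 2381 changed rows: without both bright arrays 1942 rows passed, of which 1826 were among the 2381, and with brightness as a block 2373 passed. In the bright pair alone, 1810 of those 1942 rows (93.2%) differed in the same direction, and the fold changes of the pair and of the other 8 arrays had a correlation of 0.716 across genes, which are not independent replicates. Chance at the level of arrays is unlikely: of 100 splits of the arrays into 5 and 5, drawn from 126, only the real one gave as many calls. The highest other count was 1. Splits that mix the groups carry the group difference in their spread, so the gap between 1 and 2381 does not measure the strength of the evidence. If the samples of a group shared a culture, a chance difference between cultures is not covered, and the exposure to silica remains the explanation that the design names.

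Of 208 tests of named genes, 2 groups for each of 104 genes, 9 exceeded the value, where chance would give about 10.4. Single control arrays stood apart in 5 genes. Replicate 3 was low for *ADM* (11.50 against a group median of 11.81 on the log2 scale, share 0.888) and *DDX21* (10.49 against 10.84, share 0.806) and high for *COX7B* (10.53 against 9.49, share 0.731). Replicate 4 was low for *BAAT* (8.38 against 8.71, share 0.783), and replicate 5 was high for *XBP1* (9.15 against 8.96, share 0.726). Single silica arrays stood apart in 4 genes. Replicate 3 was low for *GEM* (9.46 against 10.23, share 0.835) and high for *TNS3* (10.42 against 9.94, share 0.792). Replicate 5 was low for *DHCR7* (8.05 against 8.32, share 0.820), and replicate 2 was high for *STAT2* (8.38 against 8.23, share 0.789).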

How the results depend on the processing

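Settings that took the background from all rows, used scan brightness, a signal filter or all rows of the authors' values were chosen after seeing the data. The counts of changed rows (2381), of rises (972), of falls (1409), of 2-fold changes (403) and of lists called (12) stayed within 1.5 times under most settings. The count of 2-fold changes was 159 without background correction, 200 with normexp and an offset of 50, 201 with the background taken from all rows, 108 in the authors' values of the same rows and 109 in all of their rows. Median scaling gave 596 rises. Without normalization between arrays there were 188 changed rows, 149 higher and 39 lower, all 188 at least 2-fold. Without normalization each group kept 1 bright array, which widens the spread within groups. The median signal was 188 on that control array and 189 on that silica array, against 67.8 to 75.8 on the others. How much of the loss of calls came from this was not tested. An adjusted p under 0.01, a stricter threshold by construction, left 1398 rows, 599 higher and 799 lower. Fry, which asks a different question, called 19 lists. Leaving out 1 array at a time gave 1990 to 2236 changed rows, 828 to 921 higher, 1162 to 1334 lower, 393 to 433 at least 2-fold and 10 to 12 lists. DNA repair (adjusted p from 1.2e-04 to 0.122 over its settings) lost its call without control replicate 1 (0.0641) or 5 (0.0680) or silica replicate 4 (0.0541) or 5 (0.0734), without normalization (0.122), with detection on all 10 arrays (0.101), with an estimated correlation (0.0869) and in all rows of the authors' values (0.0890). Ribosome biogenesis (from 0.0021 to 0.135) lost it without control replicate 4 (0.0524) or silica replicate 4 (0.0587) and in the same 4 other settings (0.0916, 0.0968, 0.135 and 0.0613). The lowest p of both came from fry. Lysosome and autophagy, DNA replication and oxidative phosphorylation gained calls without the detection filter (0.0354, 0.0126 and 0.0223; over their settings 0.0120 to 0.232, 4.1e-06 to 0.468 and 7.1e-04 to 0.953) and with fry, and the first of them also with detection on all 10 arrays (0.0352). No list or named gene reversed past its threshold. Over 27 settings the 108 named genes gave 2667 values on the same side of the threshold, 207 that lost the call and 12 that gained it. Of the genes, 37 lost it only without normalization, and 14 lost it when some single array was left out, *RPL7* and *PMVK* for each of 8 arrays. The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at 0.03, 0.09, 0.00, -0.04 and -0.16 for replicates 1 to 5, and 2 of 10 arrays matched their own number best. A replicate block gave 2002 changed rows and 402 at least 2-fold, and 12 lists. A slide block was not run, since no column names a slide. Signal over background limits the fold changes of dim genes. Among the named genes that passed, 46 shrank by over 1.5 times with the background taken from all rows, 28 without background correction and 20 with normexp and an offset of 50. In the authors' values of the same rows, whose transform is unknown, 50 did. Examples with the background from all rows are *SPRY4* (2.09 to 0.28), *PMAIP1* (2.21 to 0.32), *NEU1* (1.23 to 0.21) and *ANKRD1* (1.12 to 0.15), and *IL6* went from 5.57 to 3.09 in the authors' values.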

Other observations

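The gene families and the tests of S phase and of the floor described here were chosen after the values had been seen, and the members named fall outside the rule for named genes. The families were formed from gene symbols and were compared with 10000 random lists of rows matched on mean signal. Since the families were chosen on these same values, a median outside the random lists is not evidence against chance. Genes of the clustered core and linker histones were higher in silica. Of 23 measured 15 rose and 0 fell, with a median log2 fold change of 0.79 where 95% of the random lists lay between -0.17 and 0.12. *H2AC18* rose by 2.10 (7.47 ± 0.11 against 9.56 ± 0.34, SD), *H4C2* by 2.02 and *H1-2* by 1.35. *H4C3*, the brightest member, had 0.06 and did not pass (13.42 ± 0.09 against 13.48 ± 0.15, SD). Several that rose were near the floor in control cells, such as *H4C2* (5.05) and *H4C5* (4.69). The median below is that of the whole family. The median was 0.67 with median scaling and 0.74 with cyclic loess, but 0.24 in the authors' values of the same rows and 0.08 with the background taken from all rows, where 15 and 14 members rose. Without normalization 3 rose, with a median of 0.67, and without the detection filter 17 of 64 rose, with a median of 0.12. KLF transcription factor genes were also higher, 6 of 8 measured, 3 of which (*KLF2*, *KLF6* and *KLF10*) are on the immediate early list. *KLF11*, which is not, had 1.32. With median scaling 5 KLF genes rose, with cyclic loess 6 and without normalization 1, and 0 fell.

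HOX genes, which encode transcription factors of body patterning, were lower. Of 18 measured 8 fell and 1 rose, with a median of -0.41 where 95% of the random lists lay between -0.19 and 0.16. *HOXB8* had -1.19, *HOXC8* -1.14 and *HOXB5* -1.04, and *HOXA5* rose by 0.56. The median was -0.45 with median scaling (9 fell and 0 rose) and -0.38 with cyclic loess (8 fell and 1 rose), and -0.07 in the authors' values of the same rows, where 6 fell and 1 rose. With the background taken from all rows it was -0.03, and 7 fell and 1 rose. Without normalization 0 of the HOX genes passed in limma, with a median of -0.47, and without the detection filter 9 of 39 fell, with a median of -0.10. Zinc finger genes named ZNF with a number shifted slightly. Of 183 measured 44 fell and 10 rose, with a median of -0.13 where 95% of the random lists lay between -0.07 and 0.03. Their distance below the median of all rows was -0.10, and it was -0.09 with median scaling, -0.03 in the authors' values of the same rows and -0.01 with the background taken from all rows. With detection on all 10 arrays it was -0.02, and without normalization 2 rose and 2 fell. Genes of box C/D small nucleolar RNAs went both ways, with 5 of 20 higher and 2 lower. *SNORD35A* had the largest change, 3.01.

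More cells in S phase, when replicating cells make histone messages, are a candidate explanation for the histone genes. That could raise DNA replication genes too, but 0 of 27 rose and 6 fell, and their median was -0.08. Of 26 mitosis genes 15 fell and 0 rose. These are messages of other genes and do not count the cells in S phase, so they cannot exclude this explanation. For the measured members a trend shared by equally bright rows is argued against, since random lists of such rows had a median of -0.02, against 0.79 for the histone genes. With the background taken from all rows these values were -0.002 and 0.08. The random lists were not matched on detection, and *H4C5*, detected on 0 control and 5 silica arrays, passed the filter through silica alone. The comparison was not repeated without the detection filter. Transcripts of these genes normally lack a poly(A) tail, so more histone messages with such a tail may be what the arrays saw, and near-identical copies may share signal. Neither was tested here, and an effect of silica on histone transcripts remains a hypothesis.

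The excess of large rises over large falls, 75 against 4 at 4-fold or more, could come from the floor of the arrays, which hides falls of dim genes. The counts were 44 and 1 without background correction and 29 and 0 in the authors' values of the same rows. Leaving out 1 array at a time gave 71 to 77 rises and 2 to 5 falls. Among rows with a control mean of at least 8 on the log2 scale, from which a 4-fold fall stays above the floor, there were 18 such rises and 3 falls. The floor therefore does not account for the whole excess, but it may add to it among dim rows, which hold most of the rises. It could also come from forcing equal distributions on all arrays, but median scaling gave 67 rises and 5 falls, and no biological explanation was tested.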
